A study of Mus musculus with 12 samples.

How the data were processed

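RNA sequencing libraries were analysed from 12 samples of cells that the labels call HSCs, freshly isolated from wild-type mouse liver and seeded in multiwell plates. The abbreviation is not spelled out in the labels and is read here as hepatic stellate cells, the retinoid-storing pericytes of the liver. Per the labels, all cultures were kept for 12 h after isolation before the medium was changed. Riociguat, a stimulator of soluble guanylate cyclase, was then added for the last 6, 12 or 24 h before collection, and its solvent DMSO for the last 12 h. By the labels, every group was collected 24 h after the medium change, so the groups differ in the compound and in the time since it was added. The addition came 18 h after the medium change in the 6 h group and 12 h after it in both 12 h groups. In the 24 h group it coincided with the medium change. The stage of culture at addition therefore differed with exposure time. The dose is not given in the sources used here. Each of the 4 groups has 3 libraries. Nothing in the labels says that replicates came from separate animals or isolations. P-values therefore measure only the spread between these samples, which may be technical.

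The deposited table holds expected counts per gene, which the authors made from the reads. The values were whole numbers. Per the submitters' processing notes, the tools named were FastQC, fastp, Salmon and DESeq2 and the genome build was GRCm38. The notes give no role, order, version or annotation release. Salmon estimates how many fragments come from each transcript and shares reads between similar transcripts, so values of near-identical genes, such as the Serpina1 family, Prl2c2 and its copies, or overlapping genes, are uncertain. Strand handling is not given in the sources used here. The table has 53452 genes, of which 53355 matched a symbol in a table of gene names, and all of its value columns matched 1 sample each. Gene positions come from the GENCODE vM21 annotation of GRCm38.

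Library totals ranged from 12953096 counts in replicate 1 of the 6 h group to 27358893 in replicate 3 of the same group. The 12 pairs of libraries within groups were compared with a chi-square test over genes with a summed count of at least 20. Its value per degree of freedom lay between 4.08 and 16.0, so no pair was alike within sampling noise and all libraries were kept as separate samples. The highest values, 12.3 and 16.0, were those of DMSO replicate 1 with DMSO replicates 2 and 3.

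Counts were rounded to whole numbers, which changed no value, and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, glmQLFit and glmQLFTest, two-sided) in 1 fit over all 12 libraries with the group as the only term. The filter left 16036 genes. The biological coefficient of variation was 0.0798. The fit had 8 residual and 8.80 prior degrees of freedom. P-values were adjusted with the Benjamini-Hochberg method within each comparison. Genes with an adjusted p under 0.05 are called changed. No limit on the fold was set. The standard error of a log2 fold change was taken from the moderated F statistic. Levels are CPM, the counts of a gene scaled to a common library total with TMM factors, given as mean ± SD with n = 3.

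Before the data were examined, 28 gene lists were fixed: cGMP pathway, cyclic nucleotide CREB response, contractile and stellate activation, fibrillar and structural matrix, collagen processing and crosslinking, matrix degradation and inhibitors, TGF-beta response, YAP/TAZ targets, immediate early, stellate identity and quiescence, cholesterol synthesis, fatty acid synthesis, S phase, G2/M phase, inflammatory cytokines and NF-kB, interferon response, NRF2 oxidative response, p53 response, ER stress and amino acid response, hypoxia and glycolysis, oxidative phosphorylation, aryl hydrocarbon receptor targets, and markers of macrophages, endothelial cells, hepatocytes, cholangiocytes, portal fibroblasts with mesothelium, and lymphocytes. Of their 578 entries, 565 were tested. Each list was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and adjusted over the lists of the comparison. It asks whether the genes of a list move relative to all other genes. A call is given again with the correlation estimated for each list.

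Named genes were also chosen by a rule fixed beforehand. In each comparison with DMSO it takes the 10 risen and 10 fallen genes with the largest fitted change among those with adjusted p under 0.05, with all libraries of one group above all of the other, a mean of at least 5 CPM in the higher group and a symbol that is no clone or predicted-gene name. Between exposure times it takes 5 and 5. It adds, whatever their p, Gucy1a1, Gucy1b1, Prkg1, Pde5a, Acta2, Col1a1, Col1a2, Col3a1, Timp1, Pdgfrb, Des and Lrat, and the 4 members with the smallest p of each called list.

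The steps were tested on simulated counts for the comparison of riociguat 12 h with DMSO 12 h, in which 200 genes were changed and 15684 genes passed the filter. Of the 100 genes changed by 1 on the log2 scale 85% were called, and of the 100 genes changed by 0.5, 51% were called. Besides these, 25 genes of 1 list were raised by 0.3. Of the 156 calls 7.05% fell on genes outside that list and the 200, which had no simulated change. The raised list was the only 1 of the 28 lists called. The simulated genes were drawn independently, whereas the estimated correlation in the data was 0.671 for the interferon response list in this comparison. The simulation therefore does not show how often camera calls lists of correlated genes.

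Alternatives were DESeq2 1.42.0, RLE factors, limma-voom, no low-count filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, a fit of only the 6 libraries compared, each library left out in turn, and for lists camera with an estimated correlation and fry. Comparisons with the same DMSO libraries share their chance values, so 20 data sets with no group effect were simulated to show how far 2 such comparisons are alike by chance.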

Results

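Gene expression was measured by RNA sequencing in liver-derived HSCs, read as hepatic stellate cells, after 6, 12 or 24 h with riociguat and after 12 h with the solvent DMSO, with 3 libraries per group. Library totals ranged from 12953096 to 27358893 counts, and 16036 genes were tested. Mitochondrial genes took 2.61% to 4.75% of the counts. Genes of the stellate identity list summed to 3934 ± 51.1 CPM in DMSO (SD, n = 3), and markers of other liver cells were present too, with 2130 ± 55.8 CPM for endothelial, 1925 ± 50.8 CPM for hepatocyte and 202 ± 4.81 CPM for macrophage markers. The subunits of the enzyme that riociguat stimulates were expressed, with 69.6 ± 9.06 CPM for Gucy1a1 and 68.3 ± 1.40 CPM for Gucy1b1 in DMSO (SD, n = 3).

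The comparison of riociguat 12 h with DMSO 12 h, in which both arms were exposed for the same time, asks what the compound changed. Genes of contraction and stellate cell activation fell. Acta2, which encodes alpha smooth muscle actin (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590, GRCm38), went from 484 ± 57.5 CPM in DMSO to 126 ± 8.62 CPM (SD, n = 3), a log2 fold change of -1.94 ± 0.09 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.67e-10). The actin-binding gene Tagln fell by 1.55 ± 0.09 on the log2 scale (SE), and the myosin light chain gene Myl9 fell by 1.43 ± 0.10. Cnn2, another actin-binding gene, fell from 374 ± 22.3 to 188 ± 9.79 CPM (SD, n = 3). Of the 24 genes of the contractile and stellate activation list 20 fell and none rose (21 fell when adjusted over the list alone). The list was called down (camera adjusted p = 6.88e-78, and adjusted p = 0.0017 with an estimated correlation).

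**Figure D1:**
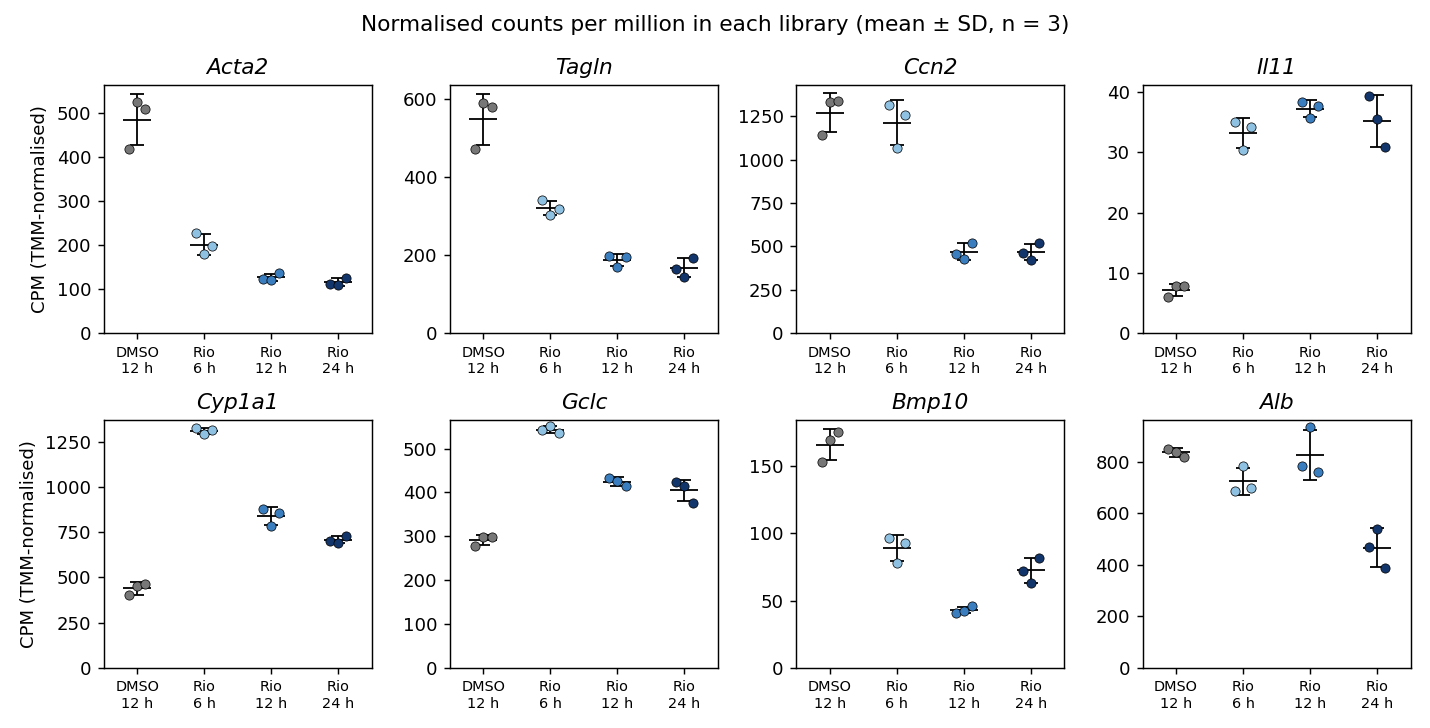
TMM-normalised CPM (vertical axes, starting at 0) of 8 genes in the 4 groups (horizontal axes; Rio stands for riociguat), with 1 point per library and the mean ± SD of 3 libraries in black. Acta2 fell from 484 CPM in DMSO to 116 CPM at 24 h, Il11 rose at every exposure time, Cyp1a1 and Gclc were highest at 6 h, and Alb fell at 24 h.

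Genes that report on YAP and TAZ activity also fell at 12 h. Ccn2 and Ccn1, which encode matricellular proteins, fell by 1.44 ± 0.09 and 1.14 ± 0.06 on the log2 scale (SE, n = 3 per group), and Ankrd1 fell by 1.29 ± 0.07 from 980 ± 54.3 CPM (SD). In the YAP/TAZ targets list 14 of 22 genes fell and 1 rose (17 and 1 adjusted over the list alone), with a camera adjusted p of 1.3e-37 (adjusted p = 0.00228 with an estimated correlation). The TGF-beta response list was called down (camera adjusted p = 2.33e-11, and adjusted p = 0.0131 with an estimated correlation), with 8 of 21 genes lower and 1 higher (11 and 2 adjusted over the list alone). Its member Thbs1, a secreted activator of latent TGF-beta, fell by 1.59 ± 0.09. The matrix degradation and inhibitors list was called down (camera adjusted p = 1.34e-07, and adjusted p = 0.00308 with an estimated correlation), with 6 of 22 genes lower (6 lower and 1 higher adjusted over the list alone), led by the metalloproteinase inhibitor gene Timp3, which fell by 1.40 ± 0.08. Srf, the transcription factor of actin-responsive genes, fell by 0.64 ± 0.07. Among genes of the immediate early list, 6 of 23 fell and 1 rose (10 and 2 adjusted over the list alone, camera adjusted p = 0.000123, and adjusted p = 0.0256 with an estimated correlation). Plk2 fell by 0.69 ± 0.06. It belongs to the p53 response list, which had 7 of 22 genes lower (12 lower adjusted over the list alone, camera adjusted p = 3.12e-07, and adjusted p = 0.0025 with an estimated correlation).

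Matrix genes moved in both directions at 12 h. The fibrillar and structural matrix list had 8 of 27 genes lower and 5 higher (11 and 5 adjusted over the list alone), and its call was lost with an estimated correlation (camera adjusted p = 3.93e-04, and adjusted p = 0.0956 with an estimated correlation). Tnc fell by 1.02 ± 0.06 on the log2 scale, while Col3a1 rose by 0.29 ± 0.06 and Spp1, which encodes osteopontin, by 0.54 ± 0.06 (SE, n = 3 per group). Col1a1 had a log2 fold change of -0.22 ± 0.07, which did not pass the test (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0878). Col1a2 fell by 0.25 ± 0.07 (adjusted p = 0.028), a call lost without any single library of either group but DMSO replicate 1, with adjusted p up to 0.185. Des, which encodes desmin, fell by 0.45 ± 0.06. Pdgfrb, the receptor of platelet-derived growth factor, fell by 0.21 ± 0.06 (adjusted p = 0.048), a call lost with RLE factors (adjusted p = 0.0544) and, among others, without riociguat 12 h replicate 2 (adjusted p = 0.322). The collagen processing and crosslinking list was called down with 4 of 19 genes lower (4 adjusted over the list alone, camera adjusted p = 0.0144, and adjusted p = 0.365 with an estimated correlation), and this call was lost without DMSO replicate 3 (adjusted p = 0.0546) or without riociguat 12 h replicate 2 (adjusted p = 0.0707).

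Other genes rose at 12 h. Il11, a cytokine gene (ENSMUSG00000004371, chromosome 7, 4772373 to 4782859), was at 7.19 ± 1.01 CPM in DMSO (SD, n = 3) and had a log2 fold change of 2.37 ± 0.11 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.67e-10). The cyclic nucleotide phosphodiesterase gene Pde7b rose by 0.99 ± 0.08 and the peptide hormone gene Cck by 1.12 ± 0.11. Of the 9 aryl hydrocarbon receptor targets 7 rose (8 adjusted over the list alone), with Cyp1a1, a xenobiotic-metabolising cytochrome, up by 0.94 ± 0.05 (camera adjusted p = 6.62e-26, and adjusted p = 0.000103 with an estimated correlation). Of the 20 genes of the NRF2 oxidative response list 12 rose, among them Gclc, the rate-limiting enzyme of glutathione synthesis, up by 0.54 ± 0.05 (15 risen adjusted over the list alone, camera adjusted p = 3.04e-20, and adjusted p = 0.00772 with an estimated correlation). Bmp10, a ligand of the BMP family, fell from 166 ± 11.7 to 43.0 ± 2.58 CPM (SD, n = 3).

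None of Gucy1a1, Gucy1b1, Prkg1 and Pde5a passed the test at 12 h, with log2 fold changes of 0.07 ± 0.08, -0.04 ± 0.06, 0.06 ± 0.10 and 0.03 ± 0.13 (SE, n = 3 per group). The interferon response list was called up by camera (adjusted p = 0.00122) although 0 of its 27 genes passed the test. That call was lost with an estimated correlation (adjusted p = 0.633 with an estimated correlation), and the mean log2 fold change of 0.49 became -0.07 without riociguat 12 h replicate 3. In that library the genes of the list summed to 730 CPM, against 390 and 397 CPM in the others of its group. The other 17 lists did not pass, with camera adjusted p between 0.0709 and 0.918. These were cGMP pathway, cyclic nucleotide CREB response, stellate identity and quiescence, cholesterol synthesis, fatty acid synthesis, S phase, G2/M phase, inflammatory cytokines and NF-kB, ER stress and amino acid response, hypoxia and glycolysis, oxidative phosphorylation and the markers of macrophages, endothelial cells, hepatocytes, cholangiocytes, portal fibroblasts with mesothelium, and lymphocytes.

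In total 907 genes changed at 12 h, of which 349 rose and 558 fell, and 52 changed by at least 1 on the log2 scale (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The excess of falls was not kept without a low-count filter (689 rose and 594 fell) or without DMSO replicate 1 (633 rose and 629 fell). The count was 564 without DMSO replicate 2, 567 without DMSO replicate 3 and 510 without riociguat 12 h replicate 2.

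After 6 h of riociguat the question was what had changed early, against a DMSO group exposed for 12 h. Genes of xenobiotic and oxidative responses rose. Cyp1a1 (ENSMUSG00000032315, chromosome 9, 57687928 to 57703824) went from 439 ± 33.8 CPM in DMSO to 1310 ± 15.3 CPM (SD, n = 3), a log2 fold change of 1.58 ± 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.4e-11). Ahrr, the repressor of the aryl hydrocarbon receptor, rose by 1.45 ± 0.13 and Tiparp by 1.08 ± 0.07. Of the 9 aryl hydrocarbon receptor targets 8 rose (8 adjusted over the list alone), with a camera adjusted p of 1.35e-46 (adjusted p = 1.01e-05 with an estimated correlation). In the NRF2 oxidative response list 18 of 20 genes rose (18 adjusted over the list alone), among them Hmox1, which encodes heme oxygenase and rose from 3631 ± 219.5 to 6185 ± 289.6 CPM, and Gclc, up by 0.90 ± 0.05 (camera adjusted p = 1.76e-54, and adjusted p = 0.000437 with an estimated correlation).

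Cell cycle and inflammatory genes fell at 6 h. Of the 26 S phase genes 21 fell (23 adjusted over the list alone), with Rrm2 and Mcm5, which serve DNA replication, lower by a log2 fold change of -0.75 ± 0.09 and -0.65 ± 0.07 (camera adjusted p = 3.12e-24, and adjusted p = 6.66e-05 with an estimated correlation). Of the 25 G2/M phase genes 10 fell (18 adjusted over the list alone), and the proliferation marker gene Mki67 fell by 0.86 ± 0.09 (camera adjusted p = 3.44e-14, and adjusted p = 0.0446 with an estimated correlation). In the inflammatory cytokines and NF-kB list 12 of 24 genes fell and 2 rose (13 and 2 adjusted over the list alone, camera adjusted p = 4.27e-13, and adjusted p = 0.0221 with an estimated correlation). The chemokine genes Ccl2 and Cxcl12 fell by 1.12 ± 0.09 and 0.78 ± 0.07. The p53 response list had 8 of 22 genes lower (12 adjusted over the list alone, camera adjusted p = 4.94e-06, and adjusted p = 0.00476 with an estimated correlation).

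Acta2 fell by 1.27 ± 0.09 at 6 h and Tagln by 0.77 ± 0.09 (SE, n = 3 per group). Of the contractile and stellate activation list 11 of 24 genes fell and 1 rose (18 and 1 adjusted over the list alone), and of the YAP/TAZ targets list 10 of 22 fell (11 adjusted over the list alone). Both calls (camera adjusted p = 7.51e-13 and 2.49e-07) were lost with an estimated correlation (adjusted p = 0.0813 with an estimated correlation for each). Of the fibrillar and structural matrix list 13 of 27 genes fell and 1 rose (13 and 1 adjusted over the list alone, camera adjusted p = 5.17e-14, and adjusted p = 0.00476 with an estimated correlation). Col1a2 fell from 227 ± 15.5 to 139 ± 4.42 CPM (SD, n = 3), Col1a1 fell by 0.49 ± 0.07 on the log2 scale, and Col6a3 and Fbn1 fell by 0.60 ± 0.04 and 0.48 ± 0.04. The collagen processing and crosslinking list (5 of 19 genes lower, 8 adjusted over the list alone) and the TGF-beta response list (6 of 21 lower and 1 higher, 7 and 4 adjusted over the list alone) were called down with camera adjusted p of 1.8e-06 and 0.00675, and both calls were lost (adjusted p = 0.0813 and adjusted p = 0.235 with an estimated correlation). Without riociguat 6 h replicate 2 the adjusted p of the TGF-beta response list was 0.098.

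Markers of other cell types also moved at 6 h. Of the 15 endothelial markers 4 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 7.91e-05, and adjusted p = 0.0463 with an estimated correlation), and their sum was 2301 ± 70.6 CPM (SD, n = 3). The cholangiocyte markers were called down with 2 of 8 lower (3 adjusted over the list alone, camera adjusted p = 0.00675, and adjusted p = 0.235 with an estimated correlation). The summed level of the portal fibroblast and mesothelial markers fell from 567 ± 43.8 to 441 ± 15.9 CPM (SD, n = 3), lower in all 3 libraries than in any of DMSO, but camera did not call the list (adjusted p = 0.117). Il11 rose by 2.20 ± 0.11, and the imprinted genes Nap1l5 and Peg3 rose by 1.62 ± 0.15 and 1.15 ± 0.08. The kinase gene Prkg1, a target of cGMP, rose by 0.43 ± 0.10 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00759), and the adjusted p was 0.0571 without riociguat 6 h replicate 2. The other 15 lists did not pass, with camera adjusted p between 0.117 and 0.787. These were cGMP pathway, cyclic nucleotide CREB response, matrix degradation and inhibitors, immediate early, stellate identity and quiescence, cholesterol synthesis, fatty acid synthesis, interferon response, ER stress and amino acid response, hypoxia and glycolysis, oxidative phosphorylation and the markers of macrophages, hepatocytes, portal fibroblasts with mesothelium, and lymphocytes.

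At 6 h 1559 genes changed, 718 up and 841 down, with 86 changed by at least 1 on the log2 scale (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Riociguat and DMSO were added at different times, so these counts hold the compound and the time of exposure together. More genes rose than fell without a low-count filter (1034 and 952), without DMSO replicate 1 (989 and 863) and in a fit of only the 6 libraries compared (621 and 588). The count was 955 without DMSO replicate 2, 992 without DMSO replicate 3 and 1010 without riociguat 6 h replicate 2.

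After 24 h of riociguat the contractile genes were again low. Acta2 was at 116 ± 8.33 CPM (SD, n = 3), a log2 fold change of -2.06 ± 0.09 against DMSO 12 h (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.47e-10), and Tagln fell by 1.71 ± 0.09. Of the contractile and stellate activation list 19 of 24 genes fell (22 adjusted over the list alone, camera adjusted p = 5.77e-53, and adjusted p = 0.00332 with an estimated correlation). Of the YAP/TAZ targets list 15 of 22 fell and 2 rose (16 and 2 adjusted over the list alone, camera adjusted p = 3.19e-24, and adjusted p = 0.00576 with an estimated correlation), and among its members Ccn2 fell by 1.44 ± 0.09. The secreted factor gene Ccn4 fell by 1.83 ± 0.11. The TGF-beta response list had 8 of 21 genes lower and 4 higher (9 and 4 adjusted over the list alone, camera adjusted p = 5.36e-06, and adjusted p = 0.0735 with an estimated correlation). Egr1 had a log2 fold change of -0.73 ± 0.05. The immediate early list had 15 of 23 lower and 1 higher (18 and 1 adjusted over the list alone, camera adjusted p = 1.2e-10, and adjusted p = 0.00332 with an estimated correlation). The p53 response list had 12 of 22 lower (13 adjusted over the list alone, camera adjusted p = 1.16e-08, and adjusted p = 0.00332 with an estimated correlation).

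Matrix genes moved in both directions at 24 h as well. Col1a1 fell by 0.86 ± 0.07 on the log2 scale (SE) from 358 ± 5.38 CPM in DMSO (SD, n = 3). Col1a2 fell by 0.25 ± 0.07 (adjusted p = 0.0183), a call lost without DMSO replicate 2 or 3 or riociguat 24 h replicate 1 or 2, with adjusted p up to 0.131. Col3a1 rose from 316 ± 7.32 to 456 ± 32.8 CPM and Timp1, a metalloproteinase inhibitor gene, from 160 ± 4.70 to 262 ± 25.0 CPM. Spp1 rose by 1.46 ± 0.06 on the log2 scale, to 732 ± 13.6 CPM. The fibrillar and structural matrix list held 9 genes that fell and 7 that rose among 27 (10 and 9 adjusted over the list alone), and camera did not call it (adjusted p = 0.0886). Il11 rose by 2.29 ± 0.11, Cck by 1.60 ± 0.11 and Gdf10, a ligand of the BMP family, by 1.42 ± 0.09. Lrat, which makes the retinyl esters that stellate cells store, rose from 4.81 ± 1.84 to 9.08 ± 0.21 CPM (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00704). Des and Pdgfrb fell by 0.52 ± 0.06 and 0.35 ± 0.06. Gucy1a1 rose to 89.0 ± 4.26 CPM, a log2 fold change of 0.36 ± 0.08 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00666), and Gucy1b1 had a log2 fold change of 0.06 ± 0.06, which did not pass.

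Hepatocyte markers fell at 24 h. Their summed level was 1143 ± 170 CPM (SD, n = 3) against 1925 ± 50.8 CPM in DMSO, and Alb, which encodes albumin (ENSMUSG00000029368, chromosome 5, 90460897 to 90476602), fell by 0.84 ± 0.09 on the log2 scale. Of the 21 markers 18 fell (20 adjusted over the list alone, camera adjusted p = 1.33e-24, and adjusted p = 0.0478 with an estimated correlation). Lipid synthesis genes fell beside them. Of the 25 cholesterol synthesis genes 11 fell (16 adjusted over the list alone, camera adjusted p = 8.93e-07, and adjusted p = 0.0735 with an estimated correlation). Of the 16 fatty acid synthesis genes 4 fell (10 fell and 1 rose adjusted over the list alone), with Fasn, fatty acid synthase, lower at 313 ± 12.8 CPM against 422 ± 13.2 CPM (camera adjusted p = 0.00125, and adjusted p = 0.0256 with an estimated correlation).

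G2/M phase genes were higher at 24 h than in DMSO, with 13 of 25 risen (20 adjusted over the list alone) and Mki67 up by 0.52 ± 0.08 (camera adjusted p = 2.98e-10, and adjusted p = 0.0782 with an estimated correlation). Of the 9 aryl hydrocarbon receptor targets 6 rose (6 rose and 2 fell adjusted over the list alone, camera adjusted p = 1.53e-07, and adjusted p = 0.00332 with an estimated correlation), with Cyp1a1 at 707 ± 19.2 CPM. The NRF2 oxidative response list had 8 of 20 genes higher and 5 lower (10 and 5 adjusted over the list alone, camera adjusted p = 0.0481, and adjusted p = 0.428 with an estimated correlation), and without DMSO replicate 1 its adjusted p was 0.23. The oxidative phosphorylation list was called up with 5 of 23 genes higher (7 adjusted over the list alone, camera adjusted p = 0.0102, and adjusted p = 0.366 with an estimated correlation). The other 16 lists did not pass, with camera adjusted p between 0.0645 and 0.983. These were cGMP pathway, cyclic nucleotide CREB response, fibrillar and structural matrix, collagen processing and crosslinking, matrix degradation and inhibitors, stellate identity and quiescence, S phase, inflammatory cytokines and NF-kB, interferon response, ER stress and amino acid response, hypoxia and glycolysis and the markers of macrophages, endothelial cells, cholangiocytes, portal fibroblasts with mesothelium, and lymphocytes.

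At 24 h 2141 genes changed, 952 up and 1189 down, with 180 changed by at least 1 on the log2 scale (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The arms differ in exposure time here as well, and the count was 1395 without DMSO replicate 2. More genes rose than fell without a low-count filter (1352 and 1208) and without DMSO replicate 1 (1308 and 1258).

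**Figure D2:**
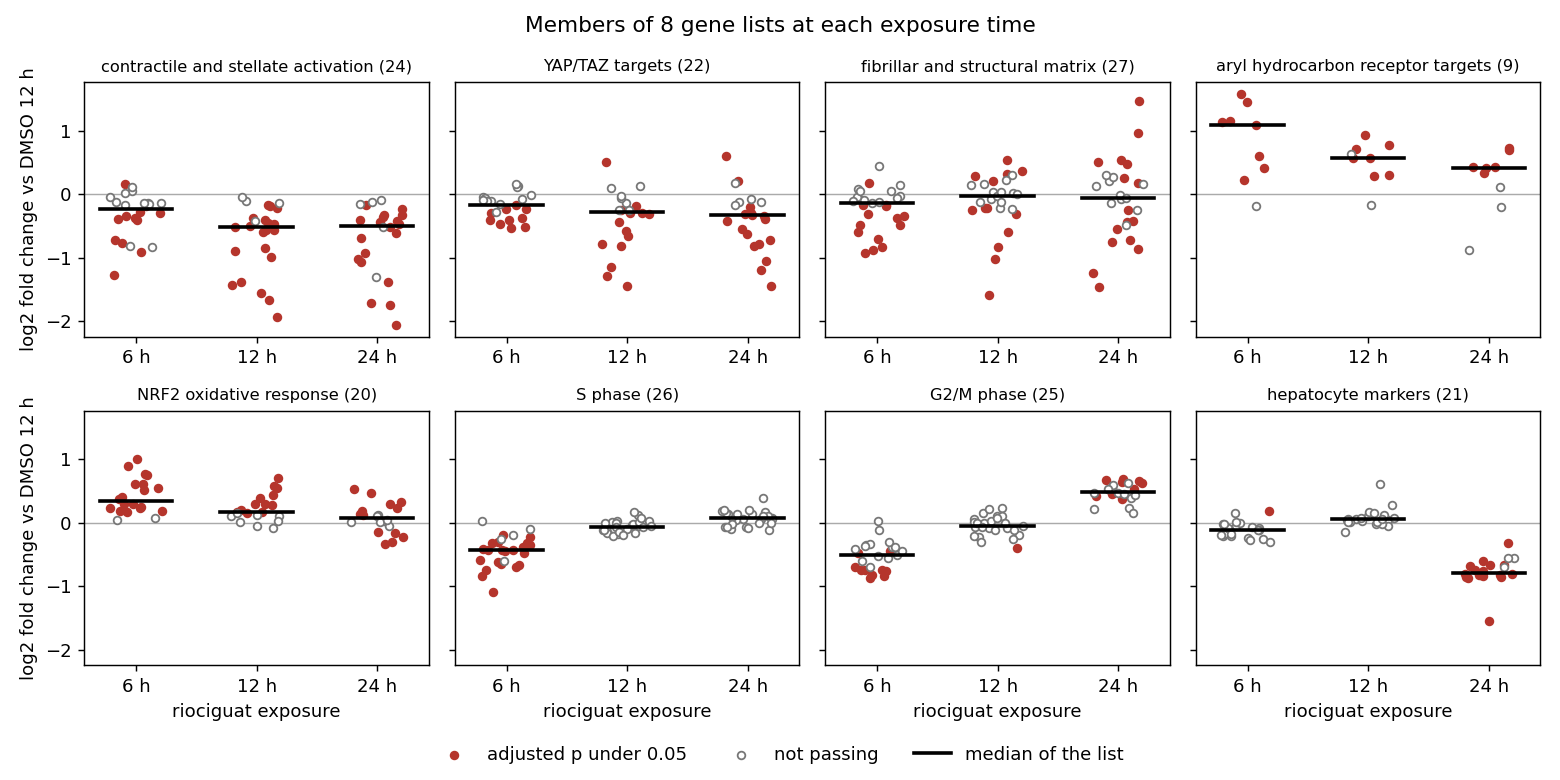
Log2 fold change against DMSO 12 h (vertical axes) of each tested member of 8 gene lists after 6, 12 and 24 h of riociguat (horizontal axes), with the number of members in brackets, filled points for genes with adjusted p under 0.05, open points for the others and a bar at the median. The median of the contractile and stellate activation list went from -0.23 to -0.51 and -0.49, and that of the aryl hydrocarbon receptor targets from 1.08 to 0.58 and 0.41.

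Riociguat 24 h was compared with riociguat 6 h to ask how levels differed with exposure time. As both are set against the same DMSO libraries, this contrast is the difference of their changes, and the DMSO levels cancel. No DMSO group was exposed for 6 or 24 h, so effects of riociguat and of the time since addition cannot be told apart. The compound was added at the medium change in the 24 h group and 18 h after it in the 6 h group. The stage of culture at addition is thus confounded too, and the groups do not form a time course from a common start. Cell cycle genes were higher at 24 h. All 25 G2/M phase genes rose (25 adjusted over the list alone), with Mki67 up by 1.38 ± 0.09 on the log2 scale (camera adjusted p = 4.26e-35, and adjusted p = 0.00682 with an estimated correlation). Of the S phase genes 24 of 26 rose (26 adjusted over the list alone, camera adjusted p = 1.78e-22, and adjusted p = 0.000346 with an estimated correlation). In the NRF2 oxidative response list 17 of 20 genes fell, with Hmox1 going from 6185 ± 289.6 to 3273 ± 49.0 CPM (SD, n = 3; 18 fell adjusted over the list alone, camera adjusted p = 4.59e-27, and adjusted p = 0.00576 with an estimated correlation). Of the aryl hydrocarbon receptor targets 7 of 9 fell and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 6.72e-12, and adjusted p = 0.0011 with an estimated correlation). Acta2 fell by 0.79 ± 0.09. In total 18 of 24 genes of the contractile and stellate activation list fell and 1 rose (18 and 1 adjusted over the list alone, camera adjusted p = 1.65e-17, and adjusted p = 0.0436 with an estimated correlation).

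Further lists differed between 24 h and 6 h. The fibrillar and structural matrix list had 12 of 27 genes higher and 4 lower (14 and 6 adjusted over the list alone, camera adjusted p = 1.11e-05, and adjusted p = 0.0451 with an estimated correlation), with Thbs2 up by 1.33 ± 0.09 and Col12a1 at 129 ± 0.51 CPM against 341 ± 0.89 CPM (SD, n = 3). Of the endothelial markers 7 of 15 fell and 3 rose (9 and 3 adjusted over the list alone), with the junction gene Cdh5 lower by a log2 fold change of -0.90 ± 0.05 (camera adjusted p = 3.56e-07, and adjusted p = 0.0161 with an estimated correlation). The immediate early list was called down with 12 of 23 genes lower and 1 higher (14 and 1 adjusted over the list alone, camera adjusted p = 6.25e-08, and adjusted p = 0.00682 with an estimated correlation). The fatty acid synthesis list was called down with 7 of 16 lower (11 adjusted over the list alone, camera adjusted p = 5.89e-05, and adjusted p = 0.0112 with an estimated correlation). The 9 calls lost with an estimated correlation were hepatocyte markers, cholesterol synthesis and YAP/TAZ targets, called down (adjusted p = 0.0678, adjusted p = 0.14 and adjusted p = 0.0678 with an estimated correlation), and stellate identity and quiescence, collagen processing and crosslinking, inflammatory cytokines and NF-kB, interferon response, oxidative phosphorylation and macrophage markers, called up (adjusted p = 0.165, 0.309, 0.0678, 0.579, 0.159 and 0.165 with an estimated correlation). Without riociguat 24 h replicate 1 the adjusted p of the interferon response list was 0.0868. That of the macrophage markers was 0.0874 without riociguat 6 h replicate 1 and 0.0619 without riociguat 24 h replicate 2.

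Between these times 2451 genes changed, 1148 up and 1303 down (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), while DESeq2 called 1243 up and 1231 down. From 6 h to 12 h 976 genes changed, 412 up and 564 down, with Tk1, a gene of DNA precursor synthesis, rising by 1.25 ± 0.15. Without a low-count filter 676 rose and 649 fell. The count was 600 without riociguat 6 h replicate 3 and 596 without riociguat 12 h replicate 2. From 12 h to 24 h 494 genes changed, 219 up and 275 down, with Il1rl1, the receptor of IL-33, rising by 1.19 ± 0.09 and Fbxo2 falling by 1.26 ± 0.14. The count was 318 without riociguat 12 h replicate 1 and 319 without riociguat 12 h replicate 2. Acta2 had a log2 fold change of -0.12 ± 0.09 from 12 h to 24 h, which did not pass the test (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.613).

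Of the genes called against DMSO, 144 rose and 191 fell at all 3 exposure times. Between 12 h and 24 h 265 genes rose in both, 427 fell in both and 6 moved in opposite directions, where independent calls would give 20.7 and 41.4. Between 6 h and 12 h 196 rose and 248 fell in both and 13 were opposite, against 15.6 and 29.3. Between 6 h and 24 h 227 rose and 274 fell in both and 119 were opposite, against 42.6 and 62.4. Across genes, which are not independent replicates, the log2 fold changes of 12 h and 24 h had a correlation of 0.556 and a covariance of 0.106. In 20 simulated data sets with no effect, sharing the DMSO libraries gave a mean correlation of 0.489 and a covariance of 0.0437 for that pair. For 6 h and 12 h the observed correlation was 0.479 against 0.493 simulated and the covariance 0.0814 against 0.0442, and for 6 h and 24 h the correlation was 0.428 against 0.488 and the covariance 0.0854 against 0.0442. In the simulations at most 1 gene was called in the same direction in 2 comparisons. With no effect simulated, few genes can pass in any comparison. This count therefore does not show how shared controls act on the overlap of changed genes. The 3 DMSO libraries are too few to be split, and how many of the shared calls stem from the shared controls was not determined.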

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

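All tests below that weigh an explanation were chosen after the results were seen; the comparisons between exposure times and the splits of the libraries were planned. Levels differed between riociguat exposure times, tested as the contrast of the riociguat groups, in which the shared DMSO group cancels. With DMSO given for 12 h only, effects of the compound, of the time since addition and of the stage of culture at addition cannot be told apart. The contrast was called for 976 genes between 12 h and 6 h and for 494 between 24 h and 12 h. Between 24 h and 6 h it was called for 2451 genes and 18 of 28 gene lists. Of the 145 genes named for the comparisons with DMSO, 89 differed between 12 h and 6 h, 57 between 24 h and 12 h and 117 between 24 h and 6 h. Most were picked by size of change or p from the same riociguat libraries, so a high share was built in. The gene counts over all genes were out of 16036 tested.

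A split of 6 libraries into 3 and 3 can be made in 10 ways, too few for a share under 0.05. The libraries were regrouped within the fit of all 12, with the other 6 kept in their groups. In each case the real split was the 1 split of 10 with the most calls. Against DMSO 12 h the real splits gave 1559, 907 and 2141 genes at 6, 12 and 24 h, and the highest of the other splits 1, 56 and 0. Between exposure times the real splits gave 976, 494 and 2451 genes for 12 h against 6 h, 24 h against 12 h and 24 h against 6 h, and the highest others 1, 1 and 3. For gene lists the real splits gave 13, 11 and 12 at 6 h, 12 h and 24 h against DMSO, and 18 for 24 h against 6 h. The highest others, with the preset correlation of camera, were 10, 8, 9 and 12. Every other split mixes the groups in unequal numbers. Part of the real difference thus stays between its sides, and part adds to the spread within them. The other splits therefore give no rate of false calls, for genes or for lists.

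Contractile and YAP/TAZ target genes were low after 12 h and 24 h of riociguat. A lower share of stellate cells would by itself lower the stellate identity genes. The median log2 fold change of that list was 0.081 at 12 h (95% interval by order statistics -0.20 to 0.18) and 0.011 at 24 h (-0.08 to 0.28). The contractile medians were -0.51 and -0.49. At 12 h the mean of the stellate list was -0.10, of the other sign. Its members moved both ways, with 3 of 21 risen and 3 fallen at 12 h and 7 and 2 at 24 h. The list mixes identity with quiescence genes, so rises in some members could hide a loss of cells. It showed no fall like that of the contractile genes, but the share of stellate cells is not settled by it. Exposure time was the same in both arms at 12 h by design and cannot be the source of the fall there, where the contractile list was called (camera adjusted p = 0.0017 with an estimated correlation). At 24 h the longer exposure and the compound stay confounded. A lower transcription of these genes under riociguat stays a hypothesis, and a change in a subset of stellate cells or in cell spreading was not tested.

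Hepatocyte marker genes were low after 24 h of riociguat, with Alb, abundant among them, at 467 ± 75.2 CPM against 837 ± 16.4 CPM in DMSO (SD, n = 3). The fall does not rest on a single library. The markers summed to 973 to 1314 CPM in the 24 h libraries, against 1883 to 1981 CPM in DMSO. The list stayed called in the 6 fits that leave 1 out (highest camera adjusted p = 5.32e-19 with the preset correlation). The estimated correlation was 0.584 and gave a camera adjusted p of 0.0478 with all libraries. It was not run with a library left out, so the stability of that call is not known. Fewer hepatocytes or less hepatocyte RNA in those cultures would lower all markers alike, and 16 of 21 (76.2%), of which 0 are in another list, lay within the 95% interval of their own error around the weighted mean log2 fold change of -0.65, with Cps1 lowest at -1.54 and Ass1 highest at -0.32. This leaves open whether the hepatocyte share, the response of those cells to the compound or the longer exposure may be the source, and these cannot be told apart. The labels give no sort that would remove hepatocytes, and how many of the markers stellate cells also express was not measured.

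Aryl hydrocarbon receptor, NRF2 and S phase genes stood apart from DMSO after 6 h. The library of lowest depth is not the only source for the first pair of lists, which were still called without it. Without this library, riociguat 6 h replicate 1, the larger of their camera adjusted p values was 3.12e-43 with the preset correlation. The estimated correlation was not run without that library. In the 12 h comparison, matched in time since addition, the aryl hydrocarbon receptor targets were called (camera adjusted p = 0.000103 with an estimated correlation). The NRF2 list was called there too (camera adjusted p = 0.00772 with an estimated correlation). Time since addition cannot be the source of those 12 h differences, but this does not show what made the 6 h differences. For S phase genes the 12 h comparison gave a camera adjusted p of 0.253 with an estimated correlation. No DMSO group was exposed for 6 h. For each of these lists, a short exposure to riociguat and the recent addition of compound and solvent therefore cannot be told apart at 6 h.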

How the results depend on the processing

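Counts of changed genes stayed within 1.5 times the reported value under DESeq2, RLE factors, limma-voom, both filters, the block and the fit of 6 libraries, except that without a low-count filter 838 genes changed between 24 h and 12 h, where 31124 genes were tested. Leaving out 1 library at a time gave 955 to 1852 genes at 6 h, 510 to 1262 at 12 h and 1395 to 2566 at 24 h against DMSO, 596 to 836 for 12 h against 6 h, 318 to 432 for 24 h against 12 h and 1772 to 2117 for 24 h against 6 h. Fewer libraries leave less to test with, but all 3 counts against DMSO rose without DMSO replicate 1, whose mitochondrial share was 4.51% against 2.99% and 2.61% in the others of its group; the cause was not tested. Either without that library or without a low-count filter, more genes rose than fell in all 3 comparisons with DMSO, the reverse of the reported balance. At 12 h the share of increases was 50.2% without the library and 53.7% without the filter, against 38.5%. The cause was not tested.

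With an estimated correlation camera called 8 lists at 6 h and 7 at 24 h against DMSO and 9 for 24 h against 6 h, and fry, which does not compare a list with other genes, called 22 at 24 h. The cause was not tested. The interferon response list at 12 h had mean log2 fold changes from -0.067 to 0.704 when 1 library was left out, and turned to -0.067 without riociguat 12 h replicate 3. Of 311 called changes of named genes 279 held under the alternatives run for genes. Of 54 list calls 32 held under those run for lists (RLE factors, no filter, the block, the estimated correlation, fry and each library left out), or 48 with the estimated correlation set aside. Lists were not tested with DESeq2, limma-voom, the 1 CPM filter or the fit of 6 libraries. Whether replicate numbers pair the samples was not settled. Deviations of same-numbered libraries correlated between -0.14 and 0.084 in 18 pairs, and those of libraries with other numbers between -0.074 and 0.098. These ranges show no clear pairing. Yet 8 of 12 libraries correlated best with a library of their number, although most of the possible partners had another number. With the replicate block 1348, 793 and 1944 genes changed at 6, 12 and 24 h against DMSO and 13, 12 and 12 lists, and the NRF2 oxidative response call at 24 h was lost (adjusted p = 0.0568). The alternative without rounding was not run, as the deposited values are whole numbers. The low-count filter kept 16036 of the 31124 genes with a count in any library, so the reported calls cover only those.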

Other observations

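The families and genes in this part were chosen after the results were seen. Phosphodiesterase genes, whose products break down cyclic nucleotides, changed in part, with 4 of 20 risen and 2 fallen at 12 h (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Pde4b, which acts on cAMP, rose at each exposure time, with log2 fold changes of 0.45 ± 0.05, 0.63 ± 0.05 and 0.68 ± 0.05 (SE) at 6, 12 and 24 h, and Pde7b rose by 0.99 ± 0.08, 0.99 ± 0.08 and 1.12 ± 0.08. Pde1a, which acts on cGMP and cAMP, fell by 0.32 ± 0.07 at 6 h and rose by 0.44 ± 0.07 at 12 h and 0.63 ± 0.07 at 24 h. The cGMP pathway list was not called against DMSO at any time and moved both ways, with 3 of 26 genes risen and 3 fallen at 6 h, 2 and 4 at 12 h and 4 and 5 at 24 h. Among those that fell, Npr3, the clearance receptor of natriuretic peptides, fell by 0.33 ± 0.08, 1.24 ± 0.08 and 0.57 ± 0.08, and Mrvi1, a substrate of cGMP-dependent kinase, fell by 0.99 ± 0.08, 1.01 ± 0.08 and 1.09 ± 0.08.

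Ligands of the BMP and GDF family moved in both directions, with 4 of 14 risen and 5 fallen at 24 h. Bmp10 fell at each time and was lowest at 12 h, at 43.0 CPM against 166 CPM in DMSO. Gdf10 and Gdf2 fell at 6 h and rose at 24 h, with log2 fold changes of -0.68 ± 0.10 and 1.42 ± 0.09 for Gdf10 and of -0.44 ± 0.06 and 0.65 ± 0.06 for Gdf2. Bmp2 rose by 0.66 ± 0.05 at 12 h and 0.78 ± 0.05 at 24 h.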
